A study of Bos taurus with 12 samples.

How the data were processed

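Poly-A RNA of bovine embryonic stem cells of the line F7 was sequenced in 12 libraries, 3 in each of 4 groups. The groups are named MC, 1/7MC, 1/7MC+Pyr and 1/7MC+Pyr+FGF. The series title speaks of feeder layers of low density, of pyruvate and of a human basic fibroblast growth factor (FGF) made as a recombinant protein. The labels do not say what MC stands for, so the names are used as given. Nothing states that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

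Per the labels' protocols, mRNA was selected from total RNA with poly-T beads, fragmented, primed with random hexamers and made into libraries with a NEBNext Ultra kit. No step that marks strand is stated, so values of overlapping, antisense and near-identical genes are uncertain. Per the submitters' processing notes, fastp 0.19.7, HISAT2 2.1.0, Subread 2.0 and featureCounts were used with the genome build bosTau9. The notes give neither the order and settings of these tools nor the gene annotation. The deposited count table holds whole-number counts per gene, and the authors applied no normalisation to it. A deposited table named TPM holds a signal that is not a TPM. Its value equals the count divided by gene length times a constant of 4.94 that is the same in all 12 libraries. Its columns sum to 66798 to 118022 and carry no correction for depth. The plan had assumed TPM there, so that signal served as an alternative only, also rescaled to the same sum in each library. All results rest on the counts.

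The count table had 19285 entries. Of these, 400 shared an Ensembl or an Entrez identifier with another entry and were left out, which removed 1.07% to 1.40% of the counts of a library. The other 18885 were kept. Entrez identifiers matched 19195 entries to a gene table of the assembly ARS-UCD2.0. That is another build than bosTau9, so it served for symbols only and no coordinates are given; 18803 of the kept entries received a symbol. SOX2, LIN28B, TDGF1, UTF1 and L1TD1 have no entry in the counts and are not analysed here. NODAL, FGF4 and DPPA2 were too low to test.

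MC replicates 2 and 3 were counted with other gene models than the other 10 libraries. Of 128 shared Ensembl identifiers, 80 to 86 carried differing counts in each of those 10 libraries and 0 did in MC replicates 2 and 3. Of 61 shared Entrez identifiers, 53 differed in MC replicates 2 and 3 and 0 in each of the other 10. TPI1 had 12040 counts in MC replicate 1 against 32 and 25 in MC replicates 2 and 3, and RPL19 had 6 against 4230 and 3495. Every comparison with MC is therefore also given with MC replicate 1 as the only MC library, which then has no replicate of its own and is assumed to vary like the libraries of the other groups. That fit tested 14361 genes.

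Total counts ranged from 27373759 to 44440972 per library. Trimmed-mean (TMM) factors ranged from 0.968 to 1.04. Genes were filtered with filterByExpr, which left 13920. Differences were tested with edgeR 4.0.16 by its quasi-likelihood F test with 1 coefficient per group, and p-values were adjusted by Benjamini-Hochberg over all genes tested. Every adjusted p of a gene is from this test unless another tool is named. Genes with adjusted p under 0.05 count as changed. Fold changes are log2 of the first group over the second, and the SE is the fold change divided by the square root of the F statistic. Log2 CPM (counts scaled to library size), with a prior count of 2, were computed here from the deposited counts. DESeq2 1.42.0 was run as another tool. R was 4.3.3, Python 3.11.15 and matplotlib 3.10.9.

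All 6 pairs of groups were compared. Before the data were examined, the comparisons, 30 gene lists, the rule for named genes and most alternatives were fixed. The lists hold shared, naive and primed pluripotency genes; neural ectoderm, mesoderm, endoderm and trophectoderm genes; fibroblast and feeder markers, endothelial and blood markers and epithelial junction genes. They also hold genes of glycolysis, of pyruvate entry and disposal, of the tricarboxylic acid cycle, of oxidative phosphorylation (nuclear and mitochondrially encoded), of mitochondrial biogenesis, of fatty acid oxidation, of cholesterol and fatty acid synthesis, and of serine and amino acid stress. The rest cover hypoxia, oxidative stress, the FGF and ERK response, FGF ligands and receptors, the TGF-beta response, the WNT response, the cell cycle, p53 and apoptosis, the interferon response, immediate early and heat shock genes, and chromatin and imprinting genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 30 lists. Each call is given with its p at an estimated correlation. Only the epithelial junction call in 1/7MC against MC and the interferon call in 1/7MC+Pyr+FGF against 1/7MC+Pyr held at that correlation. Some genes stand in more than 1 list, 9 of the shared pluripotency list and 8 each of glycolysis, hypoxia and the FGF and ERK response being the most.

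Named genes were the 6 largest rises and the 6 largest falls of each comparison. They needed a symbol, an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups. Up to 4 members of each list described, those with the smallest adjusted p, were added. A panel of 26 genes was named whatever its result, and 24 of these could be tested. The 6 genes with the largest opposite changes, and the 6 with the largest shared changes, across comparisons were also named.

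The effect of both additions on the difference between 1/7MC and MC was summarised over the genes changed in that difference. Genes that moved the opposite way were counted, and a slope through 0 of one fold change on the other was taken. As 1/7MC stands in both comparisons, 30 simulations with unchanged groups gave reference values, which can understate the real spread. After the results were seen, the 3 1/7MC libraries were also split 1 and 2 between the comparisons, in all 6 ways, so that none was shared. A lone library is then assumed to vary like the other groups.

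The pipeline was tested on simulated counts. In 1/7MC against MC, edgeR called 13, 45, 50 and 50 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 13 false calls among 13770 genes. In 1/7MC+Pyr against 1/7MC it called 8, 39, 49 and 50 of 50, with 6 false calls among 13778. In 1/7MC+Pyr+FGF against 1/7MC+Pyr it called 8, 45, 49 and 50 of 50, with 6 among 13792. A slope of -0.4 put into 13748 simulated genes came back as -0.403 for 1/7MC+Pyr against 1/7MC.

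Alternatives fixed in advance were another size factor (RLE), DESeq2, other filters, the replicate number as a block, leaving out each library, only the 6 libraries compared, a fold threshold, the signal named TPM with pseudocounts of 1 and 0.1, fry, and camera with an estimated correlation. MC replicate 1 as the only MC library, removal of a gene length trend, keeping all entries and the signal rescaled to the same sum in each library were chosen after seeing the data.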

Results

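Messenger RNA of bovine embryonic stem cells (line F7) was measured in 4 groups of 3 libraries. The series title sets cells on feeder layers of low density beside pyruvate and recombinant human basic FGF, a growth factor of stem cell media, and asks about pluripotency and metabolism. Total counts of replicates 1 to 3 were 35483180, 31709905 and 27373759 in MC, 29276694, 37092605 and 33625993 in 1/7MC, 29992124, 35486531 and 28762910 in 1/7MC+Pyr, and 44440972, 34526123 and 36601540 in 1/7MC+Pyr+FGF. Mitochondrially encoded genes took 2.42% to 4.22% of the counts. Values after ± are standard errors with n = 3 libraries per group, and fold changes are on the log2 scale. Counts of list members that rose or fell use p-values adjusted over all genes tested. Counts "adjusted over the list alone" follow where they differ.

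The first principal component of log2 CPM held 51.8% of the variance and the second 18.5%. All 3 MC libraries lay on 1 side of the first component and all 3 1/7MC libraries on the other. MC replicate 1 lay at 41.7 on that component, and MC replicates 2 and 3, which were counted with other gene models, at 82.9 and 82.6. For that reason each comparison with MC is also given against MC replicate 1 alone.

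**Figure D1:**
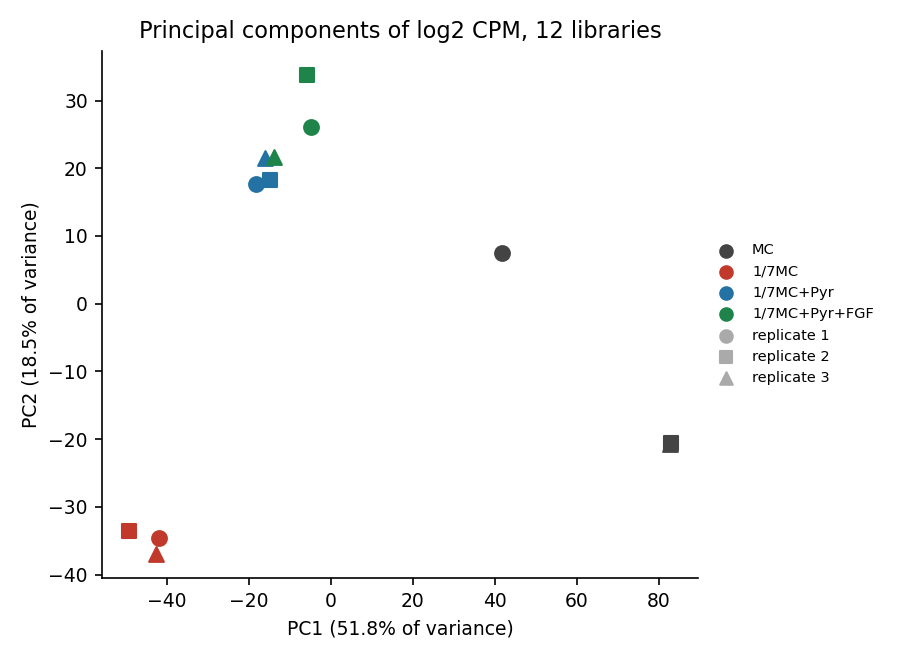
First and second principal components of log2 CPM for the 12 libraries, coloured by group, with 1 marker shape per replicate. The first component holds 51.8% and the second 18.5% of the variance; the MC and 1/7MC libraries lie at opposite ends of the first.

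The comparison of 1/7MC with MC shows what differed before any addition. Fibroblast and matrix genes were higher in 1/7MC: of 30 fibroblast and feeder markers, 28 rose and 2 fell, with a median of 1.75. POSTN, a matrix protein, rose by 4.60 ± 0.16, COL1A2, a chain of collagen I, by 3.61 ± 0.22, THY1, a surface protein of fibroblasts, by 3.04 ± 0.19, and BGN, a matrix proteoglycan, by 2.95 ± 0.17. Epithelial genes were lower: of 19 junction genes 15 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.33. EPCAM changed by -2.20 ± 0.12, the tight junction gene OCLN by -1.54 ± 0.09, the membrane protease ST14 by -2.24 ± 0.14 and the splicing regulator ESRP1 by -2.23 ± 0.14. Camera gave adjusted p = 1.02e-11 for the fibroblast list (adjusted p = 0.12 with an estimated correlation) and 4.78e-09 for the epithelial list (adjusted p = 0.0436 with an estimated correlation). Against MC replicate 1 alone, 27 of 31 fibroblast markers rose and 1 fell, 15 of 19 junction genes fell and 1 rose, and the epithelial call had adjusted p = 0.0796 with an estimated correlation.

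Of 14 shared pluripotency genes 10 fell in 1/7MC and none rose, with a median of -0.71 (camera adjusted p = 2.66e-05; adjusted p = 0.116 with an estimated correlation). With MC replicate 1 alone, 8 of 15 fell. In the same comparison the fibroblast and feeder markers rose by a median of 1.75. Of the members fixed for the pluripotency list 9 also stand in another list, EPCAM, CDH1 and ESRP1 among the junction genes. For that absence of rises, edgeR at an unadjusted p and DESeq2 gave 0 as well. LIN28A, an RNA-binding protein of stem cells, fell by 0.90 ± 0.10 on the log2 scale, the DNA methyltransferase DNMT3B by 0.69 ± 0.09, and the adhesion gene CDH1 by 2.04 ± 0.20. POU5F1, a core transcription factor of pluripotency, had a mean of 781 CPM in 1/7MC and 1093 in MC, a change of -0.49 ± 0.12 (edgeR adjusted p = 0.00693; adjusted p = 0.0585 against MC replicate 1 alone). NANOG (0.07 ± 0.15), OTX2 (-0.20 ± 0.10) and FGF2 (0.04 ± 0.18) did not pass the test.

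Glycolysis genes fell in 1/7MC, where fibroblast and feeder markers rose (median 1.75). Of 23 members 18 fell and 1 rose, with a median of -0.47 (camera adjusted p = 2.66e-05; adjusted p = 0.07 with an estimated correlation). With MC replicate 1 alone, 12 fell. Leaving out MC replicate 1 gave 2 rises over MC libraries of other gene models (TPI1 at 32 and 25 counts), and any other library 0. The glucose transporter SLC2A3 changed by -1.10 ± 0.11, hexokinase HK1 by -0.68 ± 0.08, the lactate exporter SLC16A3 by -2.56 ± 0.31 and lactate dehydrogenase LDHA by -1.17 ± 0.14. HK2 (-0.92 ± 0.14) and PKM (-0.53 ± 0.08) fell too, and so did PDK1 (-0.64 ± 0.13), which against MC replicate 1 alone missed the threshold (-0.51, adjusted p = 0.0637). MPC1, a subunit of the mitochondrial pyruvate carrier, rose by 1.08 ± 0.16. MPC2 (0.05 ± 0.17) and SLC2A1 (-0.18 ± 0.15) did not pass. Of the 22 cholesterol and fatty acid synthesis genes 15 fell and none rose (17 fell adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.07e-05; adjusted p = 0.229 with an estimated correlation). Of these genes, 7 fell against MC replicate 1 alone. SQLE (-0.92 ± 0.15), DHCR7 (-0.97 ± 0.16) and HMGCS1 (-0.72 ± 0.12), enzymes of sterol synthesis, were among them. No rise in that list was seen at an unadjusted p by edgeR, or by DESeq2.

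Signalling lists moved as well, beside the fibroblast and feeder markers (median 1.75). Of 19 TGF-beta response genes 14 rose and none fell, with a median of 1.03 (15 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2), led by BAMBI (4.78 ± 0.19), PMEPA1 (3.32 ± 0.17) and TGFB2 (2.89 ± 0.18). Testing by camera gave adjusted p = 5.73e-06 (adjusted p = 0.116 with an estimated correlation), and 12 of 20 rose against MC replicate 1 alone. Interferon response genes rose in 13 of 18 cases and fell in 2, with a median of 1.63 (camera adjusted p = 0.000857; adjusted p = 0.179 with an estimated correlation). Of 20, 12 rose and 2 fell against MC replicate 1 alone. IFI6 (4.04 ± 0.24), ISG15 (4.20 ± 0.31), OAS1Y (4.13 ± 0.28) and IRF9 (2.11 ± 0.18) showed this. Of 18 immediate early and heat shock genes 12 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.000173; adjusted p = 0.116 with an estimated correlation). Of these, 7 fell against MC replicate 1 alone. FOSB (-4.74 ± 0.24), FOS (-2.66 ± 0.16), EGR1 (-2.63 ± 0.11) and the heat shock gene HSPA1A (-1.40 ± 0.08) fell. The FGF and ERK response list was mixed, with 12 members up and 9 down of 24 (camera adjusted p = 0.491). PHLDA1 rose by 2.15 ± 0.11, SPRY2 by 1.03 ± 0.08 and ETV4 by 0.91 ± 0.15. DUSP6 rose by 0.46 ± 0.09 and missed the threshold against MC replicate 1 alone (0.35, adjusted p = 0.0892).

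PAX5 rose from 0.237 to 31.1 CPM (6.88 ± 0.49), and MAB21L1 (6.10 ± 0.28), TBX20 (6.08 ± 0.32), KIAA1755 (5.79 ± 0.45), TBX2 (5.59 ± 0.27) and RORB (5.58 ± 0.22) also rose. Of these, PAX5, TBX20, TBX2 and RORB are transcription factors of development. After FOSB, the largest falls were HEATR1 (-3.93 ± 0.68), FEZF1 (-3.61 ± 0.17), KCNIP3 (-3.50 ± 0.50), GBF1 (-3.50 ± 0.66) and LHX5 (-3.19 ± 0.16). Set against MC replicate 1 alone, HEATR1 changed by -0.70, KCNIP3 by -1.38 and GBF1 by -0.38, the last with adjusted p = 0.399. In the mesoderm list 8 of 12 genes rose and 3 fell, with a median of 1.72 (camera adjusted p = 0.0126; adjusted p = 0.116 with an estimated correlation; 6 and 2 against MC replicate 1 alone), including SNAI2 (3.25 ± 0.16) and TWIST1 (2.59 ± 0.12), transcription factors of epithelial-mesenchymal transition. The mesoderm median was 0.73 in the rescaled signal. In the endoderm list 8 of 10 rose and none fell, with a median of 0.95 (camera adjusted p = 0.000173; adjusted p = 0.0888 with an estimated correlation; 7 of 12 against MC replicate 1 alone; no fall at an unadjusted p by edgeR, or by DESeq2), including COL4A1 (2.96 ± 0.24), a basement membrane collagen. The endoderm list had 1 fall without MC replicate 1 or any 1 of the 1/7MC replicates. Fibroblast and feeder markers rose alongside both lists (28 of 30, median 1.75), and 7 members of the mesoderm list and 3 of the endoderm list also stand in another list.

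Beside the rise of fibroblast and feeder markers (median 1.75), cell cycle genes fell in 18 of 30 cases and rose in 3 (20 and 3 adjusted over the list alone), with BUB1 at -0.82 ± 0.08 and a median of -0.32 (camera adjusted p = 0.00128; adjusted p = 0.447 with an estimated correlation). Of these genes 6 fell and 1 rose against MC replicate 1 alone. Mitochondrially encoded genes fell in 7 of 13 cases and none rose (8 fell adjusted over the list alone; no rise at an unadjusted p by edgeR, or by DESeq2), with ND2 at -0.81 ± 0.11 and a median of -0.52 (camera adjusted p = 0.00506; adjusted p = 0.51 with an estimated correlation). Only 2 fell against MC replicate 1 alone. Serine and amino acid stress genes fell in 12 of 24 cases and rose in 1 (13 and 1 adjusted over the list alone), with SHMT1 at -1.39 ± 0.17 and a median of -0.25 (camera adjusted p = 0.0126; adjusted p = 0.229 with an estimated correlation). In that list 4 fell and 1 rose against MC replicate 1 alone, and 8 fell without MC replicate 2 and 2 rose without MC replicate 1. Hypoxia response genes fell in 12 of 22 cases and rose in 4, with BNIP3 at -2.50 ± 0.23, LOX at 1.82 ± 0.16 and a median of -0.47 (camera adjusted p = 0.0298; adjusted p = 0.116 with an estimated correlation; adjusted p = 0.0572 without MC replicate 1 and 0.142 under the stricter filter). Hypoxia rises numbered 2 without MC replicate 2 or 1/7MC replicates 1 or 2, and 6 fell and 2 rose against MC replicate 1 alone. WNT response genes rose in 8 of 15 cases and fell in 1, with LGR5 at 3.49 ± 0.20, DKK1 at 3.08 ± 0.18 and a median of 0.65 (camera adjusted p = 0.0297; adjusted p = 0.326 with an estimated correlation). With MC replicate 1 alone, 5 of 16 rose and the call had adjusted p = 0.0544.

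In all, 6268 of 13920 genes changed between 1/7MC and MC, 3303 up and 2965 down, and 2420 of them by at least 1 on the log2 scale. With MC replicate 1 as the only MC library 3438 changed, 2007 up and 1431 down, and 3193 changed the same way in both fits. The signal named TPM, rescaled to the same sum in each library, gave 3573 up and 2003 down, and as deposited 1411 up and 617 down. As deposited, the medians of the junction, hypoxia, cell cycle, immediate early and serine lists were -0.88, -0.20, -0.17, -0.24 and -0.10. The serine list had -0.16 in the rescaled signal. Of the panel, ETV5 (-0.35 ± 0.13), LDHB (-0.51 ± 0.19), PDHA1 (-0.28 ± 0.09), SLC16A1 (-0.37 ± 0.11) and SPRY4 (0.85 ± 0.29) passed, and each missed the threshold with single libraries left out: ETV5 with any 1 of the 6 (adjusted p up to 0.132), LDHB with any but MC replicate 1 (up to 0.129), PDHA1 with MC replicates 2 or 3 or 1/7MC replicates 1 or 3 (up to 0.0814), SLC16A1 with MC replicate 1 or 1/7MC replicates 1 or 3 (up to 0.0635), and SPRY4 with MC replicates 2 or 3 or 1/7MC replicates 1 or 2 (up to 0.117).

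**Figure D2:**
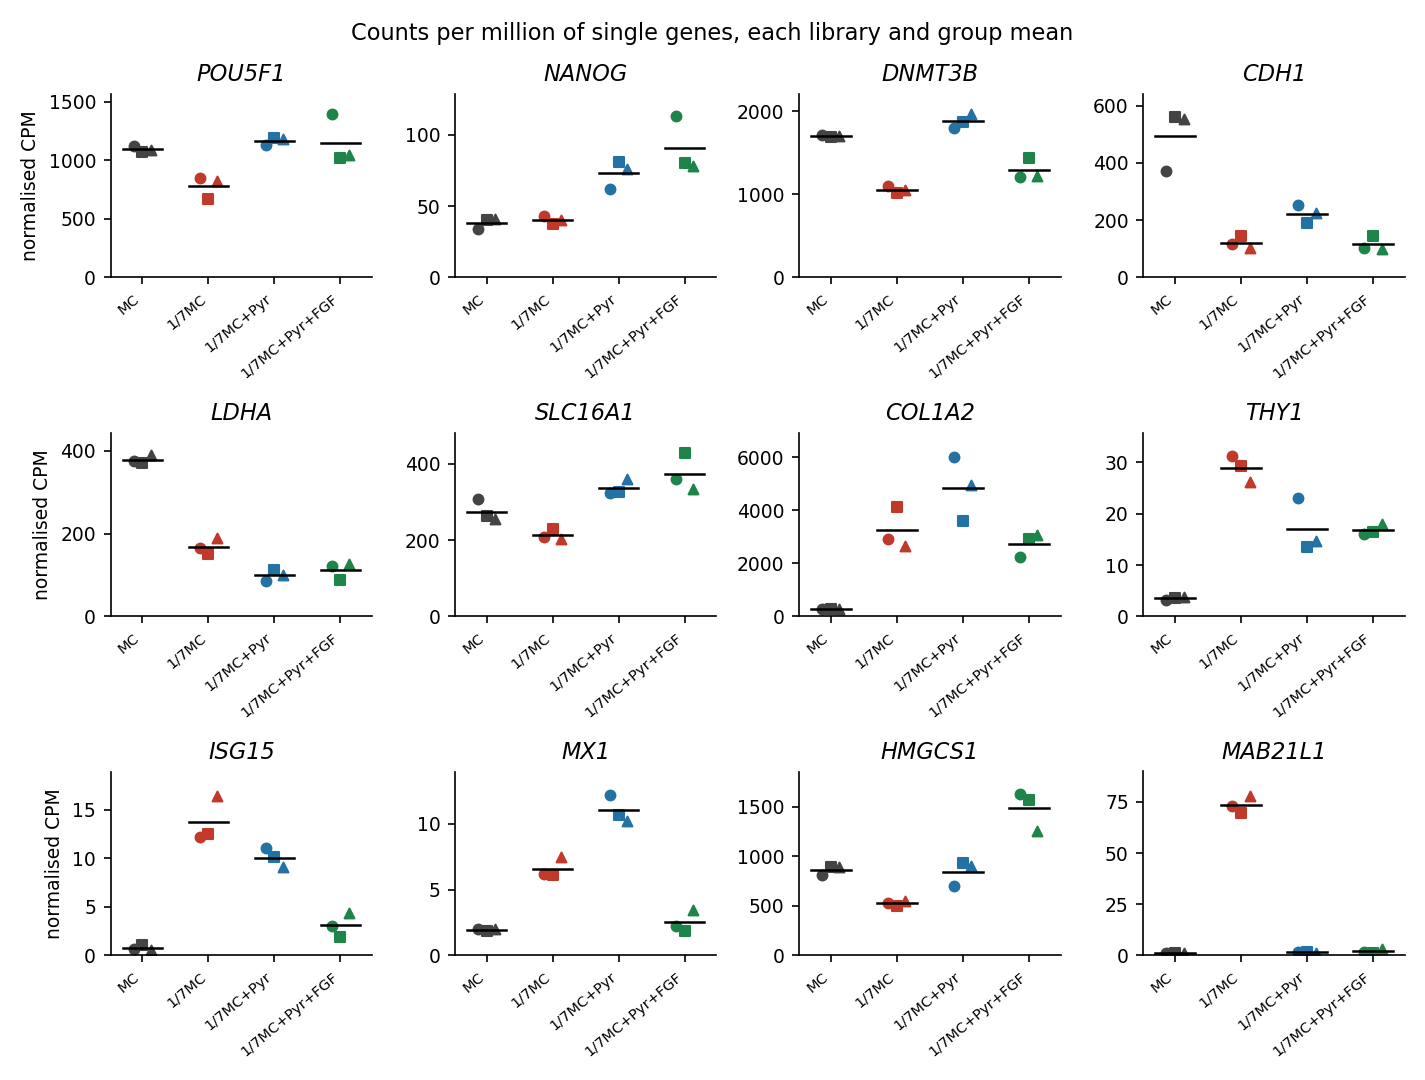
Normalised CPM of 12 genes in each library; circles, squares and triangles are replicates 1, 2 and 3, and the line is the group mean. NANOG had means of 38.4, 40.4, 73.0 and 90.5 CPM in MC, 1/7MC, 1/7MC+Pyr and 1/7MC+Pyr+FGF.

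The comparison of 1/7MC+Pyr with 1/7MC addresses what went with the pyruvate addition. Of 14 shared pluripotency genes 10 rose and none fell (12 rose adjusted over the list alone), with a median of 0.76. NANOG rose from 40.4 to 73.0 CPM (0.85 ± 0.15), POU5F1 from 781 to 1165 CPM (0.58 ± 0.12), PRDM14 by 0.91 ± 0.09, DNMT3B by 0.83 ± 0.09, SALL4 by 0.66 ± 0.12, CDH1 by 0.89 ± 0.20 and LIN28A by 0.46 ± 0.10. Cholesterol and fatty acid synthesis genes rose in 17 of 22 cases and none fell (18 rose adjusted over the list alone), with a median of 0.51. CYP51A1 (0.71 ± 0.12) and HMGCS1 (0.68 ± 0.12) were among them. Of 19 junction genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), and a median of 0.52, with CLDN4 up by 2.11 ± 0.19 and OCLN by 0.87 ± 0.09. Camera gave adjusted p = 3.71e-08 for the shared pluripotency list, 2.72e-09 for the cholesterol list and 2.79e-06 for the epithelial list. With an estimated correlation these were adjusted p = 0.114, 0.246 and 0.114. Neither of the lists without falls had one at an unadjusted p by edgeR, or by DESeq2. In the signal as deposited the medians of the 3 lists were 0.47, 0.31 and 0.23, and the rescaled signal gave 0.34 for junction genes. The 1 junction fall held only without 1/7MC+Pyr replicate 1. Cholesterol genes that rose numbered 7 without 1/7MC replicate 3 and 8 without 1/7MC+Pyr replicate 3.

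Neural ectoderm genes fell with pyruvate: of 11 genes 6 fell and none rose (7 fell adjusted over the list alone; no rise at an unadjusted p by edgeR, or by DESeq2), with a median of -0.67 (camera adjusted p = 0.00016; adjusted p = 0.191 with an estimated correlation). The transcription factors PAX6 (-2.88 ± 0.22), RAX (-3.69 ± 0.29) and PAX3 (-4.57 ± 0.48) fell. The list's median was -1.15 without 1/7MC+Pyr replicate 1 and -1.09 without 1/7MC+Pyr replicate 2. The largest falls of the comparison were TBX20 (-6.09 ± 0.32), GRP (-6.06 ± 0.36), MAB21L1 (-5.50 ± 0.27), RLBP1 (-5.27 ± 0.31), SIX6 (-4.94 ± 0.28) and HCRT (-4.28 ± 0.25). GRP and HCRT encode neuropeptides and RLBP1 a retinal protein. The largest rises were NPTX2 (2.54 ± 0.25), PLAUR (2.00 ± 0.18), R3HDML (1.80 ± 0.22), CLDN11 (1.79 ± 0.14), PPP1R16B (1.75 ± 0.09) and SLC7A8 (1.67 ± 0.25). The WNT targets LGR5 (-3.78 ± 0.21) and DKK1 (-2.47 ± 0.18) and the TGF-beta pseudoreceptor BAMBI (-2.57 ± 0.17) fell too. In their lists, 4 of 15 WNT response genes fell and 1 rose (camera adjusted p = 0.0645), and 5 of 19 TGF-beta response genes fell and 3 rose (camera adjusted p = 0.51).

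Genes of pyruvate use did not move together. Of the 22 genes of pyruvate entry and disposal 3 rose and 4 fell (camera adjusted p = 0.958). Only 1 rose without 1/7MC replicate 1, 1/7MC replicate 3 or 1/7MC+Pyr replicate 3. The monocarboxylate transporter SLC16A1 rose by 0.66 ± 0.11, while PDK4 (-3.52 ± 0.51) and PDK1 (-0.75 ± 0.14), kinases that inhibit pyruvate dehydrogenase, LDHA (-0.76 ± 0.14) and MPC1 (-0.71 ± 0.16) fell. Of 23 glycolysis genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.336), with 1 fall without 1/7MC+Pyr replicate 3. By edgeR, 0 of 20 tricarboxylic acid cycle genes and 0 of 53 nuclear-encoded oxidative phosphorylation genes changed; at an unadjusted p 1 and 2 were lower, and DESeq2 called 1 and 0. Without 1/7MC replicate 2, 1 tricarboxylic acid cycle gene fell. Of 13 mitochondrially encoded genes 3 rose and none fell (8 rose adjusted over the list alone, 9 at an unadjusted p; no fall at an unadjusted p or by DESeq2), with a median of 0.43 (camera adjusted p = 0.000323; adjusted p = 0.645 with an estimated correlation). ND2 rose by 0.47 ± 0.11. ND1 rose by 0.42 ± 0.10 and missed the threshold without 1/7MC replicate 3 (0.34, adjusted p = 0.0557). In that list 7 and 5 members rose without 1/7MC replicate 2 and 1/7MC+Pyr replicate 2, but 1 without 1/7MC replicate 3 and 2 without 1/7MC replicate 1 or 1/7MC+Pyr replicates 1 or 3. The median was 0.28 in the signal as deposited. In the serine and amino acid stress list 5 of 24 genes rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00443; adjusted p = 0.279 with an estimated correlation). SESN2 rose by 0.53 ± 0.10 and PSAT1, an enzyme of serine synthesis, fell by 1.22 ± 0.13 on the log2 scale. In the signal as deposited the median was 0.04. That list had 2 rises without 1/7MC replicate 1, 1/7MC replicate 3 or 1/7MC+Pyr replicate 3.

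Fibroblast markers went both ways with pyruvate, 6 up and 8 down of 30 (9 and 8 adjusted over the list alone; camera adjusted p = 0.825). BGN changed by -1.44 ± 0.16, FAP by -2.61 ± 0.33 and COL6A3 by 1.47 ± 0.26. The 6 rises became 2 without 1/7MC replicate 1, 1/7MC replicate 3 or 1/7MC+Pyr replicate 1, 3 without 1/7MC+Pyr replicate 3 and 10 without 1/7MC replicate 2, and the 8 falls became 5 without 1/7MC+Pyr replicate 3. COL1A1 (0.70 ± 0.27), COL3A1 (-0.12 ± 0.19) and VIM (-0.14 ± 0.13) did not pass. ETV5 rose by 0.51 ± 0.13 and missed the threshold without 1/7MC replicate 3 or 1/7MC+Pyr replicates 2 or 3 (adjusted p up to 0.0769). The panel genes not yet named for this comparison did not pass, from -0.40 ± 0.18 in FGF2 to 0.41 ± 0.14 in HK2. In all, 2525 genes changed, 1125 up and 1400 down, and 771 by at least 1 on the log2 scale. The count was 1648 without 1/7MC replicate 1, 1467 without 1/7MC replicate 3 and 1423 without 1/7MC+Pyr replicate 3. The signal named TPM as deposited gave 136 up and 422 down, with the median of all genes shifted by -0.10.

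The comparison of 1/7MC+Pyr+FGF with 1/7MC+Pyr addresses what went with the FGF addition. Interferon response genes were lower: 10 of 18 fell and none rose (14 fell adjusted over the list alone), with a median of -1.64. The antiviral gene MX1 changed by -2.14 ± 0.21, OAS1Y by -2.02 ± 0.24, IFI6 by -1.86 ± 0.20 and IRF9, a transcription factor of interferon signalling, by -1.30 ± 0.17. Camera gave adjusted p = 1.12e-14 (adjusted p = 0.0362 with an estimated correlation). No rise was seen at an unadjusted p by edgeR, or by DESeq2, and 8 or 9 members fell with any 1 of the 6 libraries left out. In the signal as deposited the median was -0.76. Fibroblast and feeder markers had 8 falls of 30 and a median of -0.30 here. With MC replicate 1 as the only MC library in the fit, 12 of 20 fell and the list had adjusted p = 0.178 with an estimated correlation.

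Of 22 cholesterol and fatty acid synthesis genes 8 rose with FGF and none fell (13 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2), with a median of 0.39 (camera adjusted p = 7.09e-08; adjusted p = 0.303 with an estimated correlation). As deposited, the signal gave 0.60. HMGCS1 rose by 0.82 ± 0.12 and MVD by 0.58 ± 0.09. FDFT1 rose by 0.55 ± 0.10, with adjusted p = 0.0674 without 1/7MC+Pyr replicate 1. Rises in the list numbered 2 without 1/7MC+Pyr replicate 1, 5 without replicate 2 and 3 without replicate 3 of that group, and 3 and 4 without 1/7MC+Pyr+FGF replicates 1 and 2. ACSS2, which makes acetyl-CoA from acetate, rose by 0.95 ± 0.10. The other large rises were MMP3 (1.42 ± 0.26; adjusted p = 0.079 without 1/7MC+Pyr replicate 1), WNT2B (1.09 ± 0.14), BAMBI (1.07 ± 0.16), KRT18 (0.91 ± 0.13) and PRPH (0.88 ± 0.09). Beside the interferon genes, the largest falls were RUNX2 (-1.95 ± 0.21), SPHK1 (-1.79 ± 0.26) and COL6A3 (-1.75 ± 0.27).

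Fibroblast markers fell in 8 of 30 cases with FGF and none rose (12 fell adjusted over the list alone; no rise at an unadjusted p or by DESeq2), with a median of -0.30 (camera adjusted p = 3.67e-05; adjusted p = 0.38 with an estimated correlation; fry adjusted p = 0.0668). Of 19 junction genes 5 fell and 2 rose (10 and 2 adjusted over the list alone), with EPCAM at -1.07 ± 0.11, ESRP1 at -0.99 ± 0.14 and CLDN7 at -0.91 ± 0.16 against KRT18, and a median of -0.35 (camera adjusted p = 0.000457; adjusted p = 0.276 with an estimated correlation). Of 14 shared pluripotency genes 4 fell and none rose (4 and 1 adjusted over the list alone; 1 rose at an unadjusted p and 0 by DESeq2), with a median of -0.13 (camera adjusted p = 0.0115; adjusted p = 0.38 with an estimated correlation; adjusted p = 0.0755 without 1/7MC+Pyr+FGF replicate 3). DNMT3B fell by 0.54 ± 0.09 on the log2 scale. CDH1 changed by -0.95 ± 0.20, and missed the threshold without 1/7MC+Pyr replicates 1 or 3 or 1/7MC+Pyr+FGF replicates 1 or 3 (adjusted p up to 0.125). Fibroblast falls numbered 1 without 1/7MC+Pyr replicates 1 or 3 or 1/7MC+Pyr+FGF replicates 1 or 2, and 3 without 1/7MC+Pyr+FGF replicate 3. Junction falls numbered 3 without 1/7MC+Pyr replicates 1 or 3 and 8 without replicate 2. Junction rises numbered 1 without 1/7MC+Pyr replicates 1 or 3 or 1/7MC+Pyr+FGF replicates 1 or 3. The junction median was -0.54 without 1/7MC+Pyr+FGF replicate 2. The shared pluripotency median was -0.31 without that library, -0.24 without 1/7MC+Pyr replicate 2 and -0.30 in the rescaled signal. In the signal named TPM as deposited, where the median of all genes was shifted by 0.24, the medians of these 3 lists were 0.00, 0.14 and 0.17.

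None of the direct FGF targets of the panel passed: SPRY4 (0.15 ± 0.29), DUSP6 (-0.01 ± 0.09), ETV4 (-0.17 ± 0.15) and ETV5 (-0.23 ± 0.13). By edgeR 0 of 24 FGF and ERK response genes changed (2 up and 2 down at an unadjusted p, 1 and 1 by DESeq2), with camera adjusted p = 0.344, or 0.047 without 1/7MC+Pyr+FGF replicate 2. Without 1/7MC+Pyr replicate 2 1 of them fell, and 2 did without 1/7MC+Pyr+FGF replicate 3. For FGF ligands and receptors edgeR called 0 of 15, with 1 up and 3 down at an unadjusted p and 0 by DESeq2 (camera adjusted p = 0.967). POU5F1 (-0.02 ± 0.12), NANOG (0.31 ± 0.15), LIN28A (0.03 ± 0.10) and the panel's metabolic genes did not pass either. MPC1 and MPC2 had the largest of these values, at 0.37 ± 0.16 and 0.37 ± 0.17.

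Camera called several energy and growth lists higher with FGF in which edgeR called 0 members. The medians were 0.31 over 53 nuclear-encoded oxidative phosphorylation genes (camera adjusted p = 6.12e-08), 0.21 over 30 cell cycle genes (4.61e-07), 0.19 over 20 tricarboxylic acid cycle genes (0.000975), 0.21 over 22 oxidative stress genes (0.00169), 0.12 over 23 glycolysis genes (0.0167) and 0.16 over 22 genes of pyruvate entry and disposal (0.0304). With an estimated correlation these had adjusted p = 0.516, 0.33, 0.38, 0.38, 0.303 and 0.38. At an unadjusted p 11, 13, 3, 5, 2 and 5 members were higher, and DESeq2 called 2, 5, 0, 0, 0 and 0. Adjusted over the list alone 7 cell cycle genes rose and none of the other lists. Leaving out 1/7MC+Pyr replicate 2 gave 1 cell cycle rise. CYCS (0.68 ± 0.21) and ATP5F1B (0.29 ± 0.09) had the smallest p of the respiratory list. Its median was 0.15 with a gene length trend removed and 0.12 without 1/7MC+Pyr+FGF replicate 1. With all genes split into 5 length groups, the shortest had a median of 0.14 and the longest -0.13. In the order above, the 6 medians were 0.19, 0.11, 0.09, 0.10, 0.02 and 0.05 in the rescaled signal, and 0.54, 0.41, 0.40, 0.39, 0.38 and 0.31 as deposited. The pyruvate entry median was 0.25 without 1/7MC+Pyr replicate 2. Without 1/7MC+Pyr replicate 2 glycolysis had adjusted p = 0.0607, and pyruvate entry had 0.185 and 0.0582 without 1/7MC+Pyr replicate 1 and 1/7MC+Pyr+FGF replicate 1, and was not called under the stricter filter. By fry the nuclear, tricarboxylic acid, oxidative stress and pyruvate entry lists were not called (adjusted p = 0.210, 0.0826, 0.0668 and 0.0854). The serine and amino acid stress list was called too (camera adjusted p = 0.0115; adjusted p = 0.330 with an estimated correlation; adjusted p = 0.118 without 1/7MC+Pyr+FGF replicate 2). Of its 24 genes 2 rose and none fell (5 rose adjusted over the list alone; 1 fell at an unadjusted p and 0 by DESeq2), with PSAT1 at 0.87 ± 0.13. Only 1 rose when any of 3 libraries was left out. In all, 384 genes changed with FGF, 89 up and 295 down. DESeq2 called 863. The count was 127 and 143 without 1/7MC+Pyr replicates 1 and 3, and 149 and 239 without 1/7MC+Pyr+FGF replicates 1 and 2. The signal as deposited gave 36 up and 20 down.

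**Figure D3:**
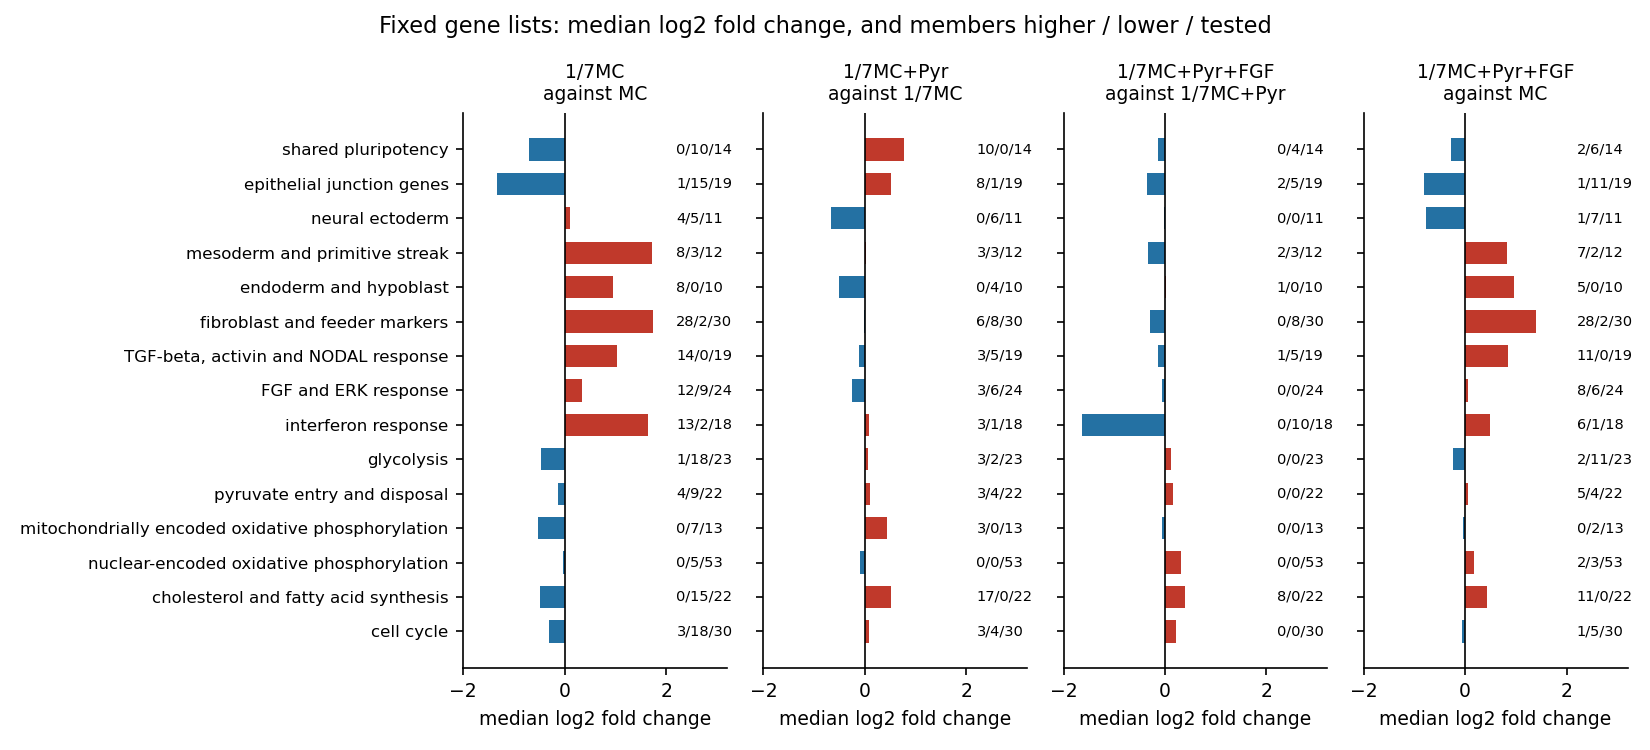
Median log2 fold change of 15 gene lists in 4 comparisons, with the numbers of members higher, lower and tested beside each bar. The interferon response list had medians of 1.63 in 1/7MC against MC and -1.64 in 1/7MC+Pyr+FGF against 1/7MC+Pyr.

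Both additions together were compared with 1/7MC, a comparison in which fibroblast and feeder markers had a median of -0.25. Of 22 cholesterol and fatty acid synthesis genes 20 rose and none fell (21 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2), with a median of 0.90. HMGCS1 rose by 1.50 ± 0.13, CYP51A1 by 1.13 ± 0.12 and ELOVL6 by 0.94 ± 0.10. Of 14 shared pluripotency genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.55. PRDM14 rose by 1.17 ± 0.09, NANOG by 1.16 ± 0.15, SALL4 by 0.59 ± 0.12, POU5F1 by 0.56 ± 0.12 and LIN28A by 0.49 ± 0.10, while EPCAM fell by 0.83 ± 0.11 on the log2 scale. Falls in that list numbered 1 without 1/7MC+Pyr+FGF replicate 3. Of 24 serine and amino acid stress genes 13 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.43. TRIB3 (1.48 ± 0.22), PSPH (0.68 ± 0.12) and SESN2 (0.59 ± 0.10) rose. The 1 fall was lost without 1/7MC replicates 1 or 3 or 1/7MC+Pyr+FGF replicate 2. Interferon response genes fell in 12 of 18 cases and rose in 1 (13 and 1 adjusted over the list alone), with a median of -1.43. OAS1Y (-2.32 ± 0.25) and ISG15 (-2.14 ± 0.26) fell. The interferon median was -0.79 in the signal as deposited. Testing by camera gave adjusted p = 2.3e-13, 0.00959, 9.18e-05 and 1.8e-05 for these 4 lists, and with an estimated correlation adjusted p = 0.151, 0.37, 0.151 and 0.151.

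Neural ectoderm genes fell in 6 of 11 cases with both additions and none rose (8 fell adjusted over the list alone; no rise at an unadjusted p or by DESeq2), with a median of -0.75 (camera adjusted p = 0.000203; adjusted p = 0.151 with an estimated correlation). PAX6 changed by -3.26 ± 0.22 and RAX by -3.20 ± 0.28. The list's median was -1.28 and -1.20 without 1/7MC+Pyr+FGF replicates 3 and 1, and -1.14 without 1/7MC replicate 3. The largest falls were TBX20 (-6.25 ± 0.32), GRP (-5.92 ± 0.35), MAB21L1 (-5.23 ± 0.26), SIX6 (-4.74 ± 0.27), RLBP1 (-4.73 ± 0.29) and PMEL (-4.30 ± 0.11), and the largest rises MMP3 (3.42 ± 0.29), NPTX2 (2.55 ± 0.25), PPP1R16B (2.32 ± 0.09), S100A2 (2.28 ± 0.25), APLN (2.14 ± 0.38) and KLHL4 (1.97 ± 0.19). In the FGF and ERK response list 10 of 24 fell and 1 rose (12 and 3 adjusted over the list alone), with FOS at -1.20 ± 0.16, SPRY1 at -0.78 ± 0.12 and DUSP5 at 0.99 ± 0.17 (camera adjusted p = 0.0293; adjusted p = 0.499 with an estimated correlation; adjusted p = 0.104 without 1/7MC+Pyr+FGF replicate 1). Rises in it numbered 2 without 1/7MC+Pyr+FGF replicates 1 or 3. Fibroblast markers fell in 10 of 30 cases and rose in 2, with a median of -0.25, and PRRX1 changed by -1.91 ± 0.20 and POSTN by -1.14 ± 0.14 (camera adjusted p = 0.0215; adjusted p = 0.563 with an estimated correlation; adjusted p = 0.169 without 1/7MC replicate 2 and 0.152 without 1/7MC+Pyr+FGF replicate 1). Leaving out these 2 libraries in turn gave medians of -0.07 and -0.11, and the signal as deposited gave -0.07. Fibroblast rises numbered 1 without 1/7MC replicates 1 or 3 or 1/7MC+Pyr+FGF replicate 2.

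Among energy lists, oxidative stress genes rose in 8 of 22 cases with both additions (10 adjusted over the list alone; median 0.30; camera adjusted p = 0.000391; adjusted p = 0.37 with an estimated correlation), led by TXNRD1 (0.60 ± 0.09) and HMOX1 (0.69 ± 0.11). Glycolysis genes rose in 4 of 23 cases and fell in 2 (median 0.23; camera adjusted p = 0.0107; adjusted p = 0.227 with an estimated correlation). SLC16A1 rose by 0.81 ± 0.11 and LDHA fell by 0.58 ± 0.14 on the log2 scale. Mitochondrially encoded genes rose in 4 of 13 cases, with ND1 at 0.57 ± 0.10 and ND2 at 0.55 ± 0.11 (median 0.43; camera adjusted p = 0.00239; adjusted p = 0.499 with an estimated correlation). Cell cycle genes rose in 12 of 30 cases and fell in 2 (17 and 2 adjusted over the list alone), with BUB1 at 0.45 ± 0.08 and CCND1 at -0.49 ± 0.10 (median 0.28; camera adjusted p = 0.000391; adjusted p = 0.476 with an estimated correlation). In that list 6 rose without 1/7MC replicate 2, and 1 fell with any library but 1/7MC+Pyr+FGF replicate 1 left out. Glycolysis falls numbered 1 without 1/7MC replicates 1 or 3 or 1/7MC+Pyr+FGF replicates 2 or 3. The rescaled signal gave medians of 0.20 for oxidative stress, 0.10 for glycolysis and 0.19 for cell cycle genes. The oxidative stress median was 0.19 without 1/7MC replicate 2, and that of mitochondrially encoded genes 0.24 without 1/7MC+Pyr+FGF replicate 2. In all, 3842 genes changed, 1656 up and 2186 down, against 853 and 2333 for the rescaled signal and 485 and 338 for the signal as deposited, whose median over all genes was shifted by 0.15. PDK1 fell by 0.55 ± 0.14 on the log2 scale (adjusted p = 0.0531 without 1/7MC replicate 3). DNMT3B (0.29 ± 0.09), DUSP6 (-0.27 ± 0.09) and VIM (-0.47 ± 0.13) passed, and each missed the threshold with single libraries left out: DNMT3B without 1/7MC replicates 2 or 3 or 1/7MC+Pyr+FGF replicate 2 (adjusted p up to 0.0819), DUSP6 without any 1/7MC replicate or 1/7MC+Pyr+FGF replicates 1 or 3 (up to 0.122), and VIM without 1/7MC replicates 2 or 3 or 1/7MC+Pyr+FGF replicates 1 or 2 (up to 0.0777). The other 15 panel genes did not pass, CDH1 (-0.06 ± 0.20) and COL1A1 (0.04 ± 0.27) among them.

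Camera called 4 more lists, beside the fibroblast median of -0.25. Mesoderm genes fell in 5 of 12 cases and rose in 1 (adjusted p = 0.0330), with TWIST1 at -0.87 ± 0.11, and 3 fell without 1/7MC replicate 2 or 1/7MC+Pyr+FGF replicate 1. WNT response genes fell in 7 of 15 cases and rose in 1 (adjusted p = 0.0293), with LGR5 at -3.87 ± 0.20. WNT falls numbered 3 or 4 when any of 3 libraries was left out. Tricarboxylic acid cycle genes rose in 6 of 20 cases and none fell (1 fell at an unadjusted p and 0 by DESeq2; adjusted p = 0.0293). Those rises numbered 1 to 3 without any library but 1/7MC+Pyr+FGF replicate 2. Nuclear-encoded oxidative phosphorylation genes rose in 2 of 53 cases and none fell (0 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2; adjusted p = 0.0107). None of them rose without 1/7MC replicates 1 or 2 or 1/7MC+Pyr+FGF replicate 1, and 8 did without 1/7MC+Pyr+FGF replicate 2. With an estimated correlation the 4 lists, in this order, had adjusted p = 0.248, 0.411, 0.548 and 0.640. Without 1/7MC+Pyr+FGF replicate 1 none of the 4 was called (adjusted p = 0.0706, 0.0982, 0.107 and 0.576). Leaving out 1/7MC replicate 2 ended the mesoderm, tricarboxylic acid and nuclear calls (adjusted p = 0.0627, 0.169 and 0.233), and fry did not call the last 2 (adjusted p = 0.0643 and 0.326). Mesoderm had adjusted p = 0.0600 under the stricter filter, and WNT 0.0936 with MC replicate 1 alone.

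How far the additions moved the genes that differed between 1/7MC and MC was asked next. Of those 6268 genes, 1948 (31.1%) changed the opposite way with pyruvate and 89 the same way; independent lists of these sizes would share 572. With both additions 2553 (40.7%) moved the opposite way and 135 the same way, against 871 for independent lists. With FGF on top of pyruvate 226 moved the opposite way and 99 the same way, against 89.0. TBX20, MAB21L1, GRP, SPARCL1 (-3.90 ± 0.31 with both additions), PAX5 (-3.58 ± 0.38) and HCRT (-3.94 ± 0.24) had the largest opposite changes. Slopes of the later change on the first were -0.34 with pyruvate, -0.40 with both and -0.063 with FGF on top. In 30 simulations with unchanged groups the highest opposite counts were 0, 2 and 1, with mean slopes of -0.026, -0.025 and 0.00019. Covariances were -0.368, -0.431 and -0.0629, against simulated means of -0.0323, -0.0322 and 0.000151. The comparison of FGF on top shares no library with the first change, and the other comparisons share the 3 of 1/7MC. Splitting these 1 and 2 so that none was shared gave slopes from -0.358 to -0.271 with pyruvate and from -0.413 to -0.347 with both. Opposite genes then numbered 550 to 1182 and 928 to 1572, with at most 104 and 83 moving the same way. Covariances ran from -0.383 to -0.317 and from -0.433 to -0.402. Against MC replicate 1 alone, 1665 of 3438 genes moved the opposite way with pyruvate, 1920 (55.8%) with both and 265 with FGF on top.

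Counts of opposite genes fell to 1200 and 1184 with pyruvate when 1/7MC replicate 3 or 1/7MC+Pyr replicate 3 was left out. With FGF on top they were 133 and 142 without 1/7MC replicates 1 and 3, 72 and 92 without 1/7MC+Pyr replicates 1 and 3, 79 and 108 without 1/7MC+Pyr+FGF replicates 1 and 2, and 415 without MC replicate 1. The slopes with pyruvate and with both additions were -0.226 and -0.270 without MC replicate 1, a fit left with the 2 MC libraries counted with other gene models. They were -0.344 and -0.408 with MC replicate 1 as the only MC library. The slope with FGF on top turned to 0.0013 in the signal as deposited. It was -0.0383 and -0.0344 without 1/7MC+Pyr+FGF replicates 1 and 2, and another split of these 6 libraries gave -0.0612.

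**Figure D4:**
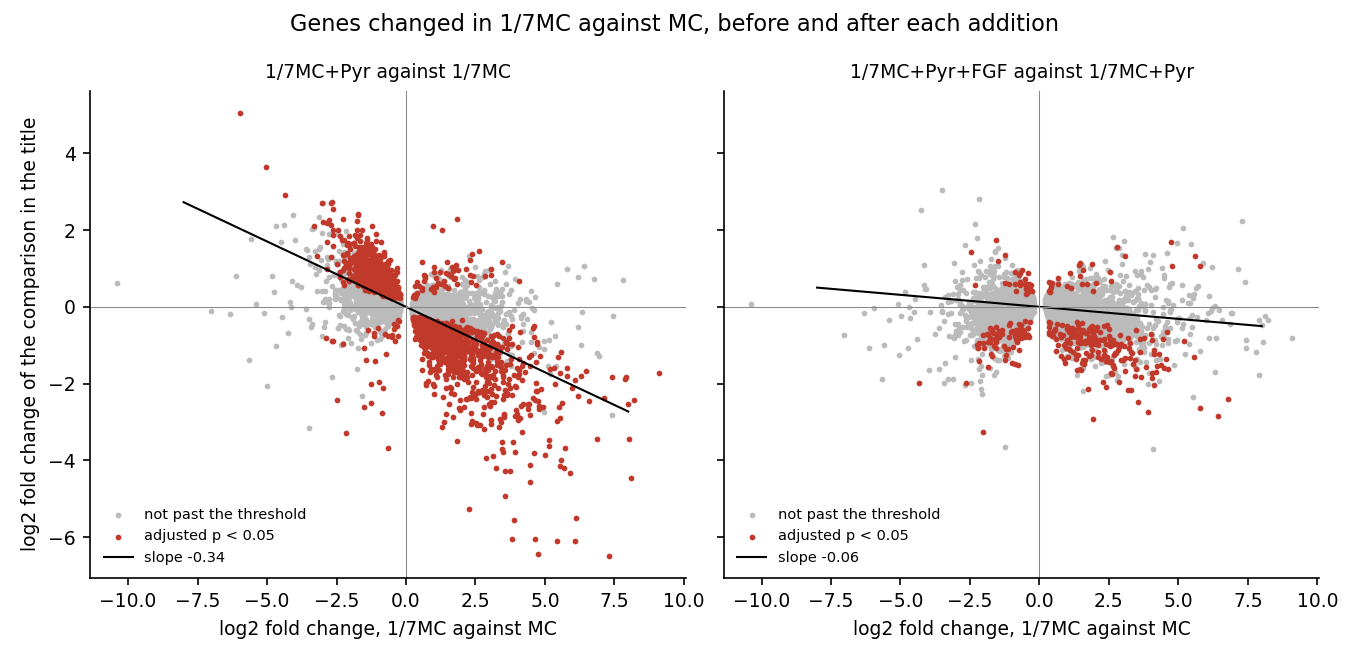
Log2 fold change of 1/7MC against MC (horizontal) and of the pyruvate and the FGF addition (vertical) for genes changed in the first; red points passed adjusted p under 0.05 in the second and the line is the slope through 0. The slope is -0.34 with pyruvate. With FGF on top of pyruvate it is -0.063, but 0.0013 in the signal as deposited, -0.0344 without 1/7MC+Pyr+FGF replicate 2 and -0.0612 in another split of the 6 libraries.

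The groups with additions were last compared with MC itself. In 1/7MC+Pyr against MC, fibroblast markers were higher, with 27 of 30 up and 2 down (28 and 2 adjusted over the list alone) and a median of 1.87. COL1A2 rose by 4.20 ± 0.22, POSTN by 4.11 ± 0.15, COL1A1 by 2.81 ± 0.29 and COL3A1 by 2.95 ± 0.20. Interferon response genes rose in 12 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone; median 1.80), TGF-beta response genes in 12 of 19 with 1 fall (13 and 1 adjusted over the list alone; median 0.88), and junction genes fell in 13 of 19 cases with 1 rise (14 and 1 adjusted over the list alone; median -0.64), EPCAM by 1.96 ± 0.11 on the log2 scale. Of 23 glycolysis genes 15 fell and none rose (15 down and 2 up adjusted over the list alone; 2 rose at an unadjusted p and 1 by DESeq2; median -0.42). LDHA went from 378 to 99.5 CPM (-1.92 ± 0.15), and PDK1 (-1.39 ± 0.14) and SLC16A3 (-2.35 ± 0.31) fell. Camera gave adjusted p = 2.57e-17, 6.87e-07, 6.87e-07, 2.19e-06 and 8.38e-05 for these 5 lists, and with an estimated correlation adjusted p = 0.0775, 0.0715, 0.0715, 0.0715 and 0.0715. In the fit with MC replicate 1 alone, 24 of 31 fibroblast markers, 11 of 20 interferon genes and 10 of 20 TGF-beta genes rose, and 9 of 19 junction genes and 9 of 23 glycolysis genes fell. Leaving out MC replicate 1 gave 3 glycolysis rises, over other gene models. The 1 interferon fall was lost without 1/7MC+Pyr replicates 2 or 3. In the signal as deposited the junction and TGF-beta medians were -0.42 and 0.53.

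Beside those markers camera called 9 more lists in this comparison. Higher were mesoderm genes, with 6 of 12 up and none down (6 and 1 adjusted over the list alone) and SNAI2 at 3.53 ± 0.16, endoderm genes, with 5 of 10 up and none down and COL4A1 at 2.76 ± 0.24, and endothelial and blood markers, with 5 of 12 up and none down and RUNX1 at 2.87 ± 0.28. They had adjusted p = 0.00213, 0.0170 and 0.0305 (0.0715, 0.178 and 0.317 with an estimated correlation). Lower were cell cycle genes, with 15 of 30 down and none up (20 down adjusted over the list alone) and BUB1 at -0.55 ± 0.08, and immediate early and heat shock genes, with 9 of 18 down and 3 up (10 and 3 adjusted over the list alone) and EGR1 at -3.53 ± 0.12. Neural ectoderm genes had 6 of 11 down and 1 up, and trophectoderm genes 5 of 14 down and 1 up, with KRT7 at -1.64 ± 0.15. Nuclear-encoded oxidative phosphorylation genes had 4 of 53 down and none up and fatty acid oxidation genes 4 of 17 down and 1 up. In the 5 lists with none the other way DESeq2 called none either, and at an unadjusted p 1 mesoderm and 1 endoderm gene fell. The 6 lower lists had adjusted p = 8.38e-05, 0.00179, 0.0170, 0.0443, 0.0173 and 0.0386, and with an estimated correlation adjusted p = 0.317, 0.178, 0.252, 0.168, 0.820 and 0.504.

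Of these calls, those of the mesoderm, cell cycle and immediate early lists held in each other fit at the preset correlation. Where MC replicate 1 stood alone for MC, 5 of 12 mesoderm, 5 of 12 endoderm and 3 of 12 endothelial genes rose, while 1 of 30 cell cycle, 5 of 18 immediate early, 5 of 13 neural, 3 of 14 trophectoderm, 1 of 53 nuclear oxidative phosphorylation and 0 of 17 fatty acid oxidation genes fell. The last 2 were not called there (adjusted p = 0.257 and 0.398), nor with a gene length trend removed (0.301 and 0.114). Removing that trend also ended the trophectoderm and endothelial calls (adjusted p = 0.0813 and 0.0644), and fry did not call the nuclear list (0.364). Under the stricter filter the neural, endoderm, trophectoderm and endothelial lists had adjusted p = 0.222, 0.0528, 0.0951 and 0.0645, and the replicate block gave 0.0562 for trophectoderm. Single libraries left out ended the other 6 calls: neural for 2 of the 6 libraries (adjusted p up to 0.0684), endoderm for 3 (0.389), endothelial for 2 (0.104), trophectoderm for 5 (0.118), nuclear for 3 (0.135) and fatty acid oxidation for 4 (0.0850). Cell cycle falls numbered 7 without MC replicates 2 or 3, with 1 rise without MC replicate 1, and immediate early rises 1 without any library but MC replicate 1. Mesoderm and endoderm had 1 fall each without 1/7MC+Pyr replicate 1, and endoderm 1 without MC replicate 1. The neural rise was lost when any of 5 libraries was left out. Trophectoderm falls and endothelial rises numbered 3 without MC replicate 2, and fatty acid oxidation falls 0 without MC replicates 2 or 3.

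Beside the fibroblast markers (median 1.87), shared pluripotency genes in 1/7MC+Pyr and MC went both ways, 3 up and 5 down of 14 (camera adjusted p = 0.456), and of 22 cholesterol genes 1 rose and 1 fell (camera adjusted p = 0.747), with 3 falls without MC replicate 1 and 0 without any other library, and 0 rises without MC replicates 2 or 3 or 1/7MC+Pyr replicate 3. NANOG was higher than in MC by 0.92 ± 0.15, POU5F1 (0.09 ± 0.12) and DNMT3B (0.14 ± 0.09) did not pass, and CDH1 fell by 1.15 ± 0.20 on the log2 scale (adjusted p = 0.0733 against MC replicate 1 alone). VIM rose by 0.89 ± 0.14. HK2 changed by -0.51 ± 0.14, with adjusted p = 0.0649 without 1/7MC+Pyr replicate 1. LIN28A (-0.44 ± 0.10), ETV4 (0.78 ± 0.15), SPRY4 (1.06 ± 0.29) and PKM (-0.46 ± 0.08) passed but missed the threshold against MC replicate 1 alone (adjusted p = 0.18, 0.0864, 0.429 and 0.0569), and SPRY4 also without MC replicates 2 or 3 or 1/7MC+Pyr replicate 3 (adjusted p up to 0.0751). The largest rises were KCNMA1 (4.88 ± 0.25), FMOD (4.74 ± 0.25), CRISPLD2 (4.65 ± 0.20), ATP6AP1L (4.57 ± 0.18), CDKN2B (4.46 ± 0.31) and COL1A2. The largest falls were ZC3H10 (-4.73 ± 0.86), FOSB (-4.36 ± 0.24), RAX (-4.33 ± 0.30), GBF1 (-3.81 ± 0.68), ACTA1 (-3.71 ± 0.17) and FEZF1 (-3.66 ± 0.18). ZC3H10 and GBF1 had -0.16 and -0.69 against MC replicate 1 alone and did not pass. In all, 3949 genes changed, 2115 up and 1834 down, with 2571 and 2616 in total without MC replicates 2 and 3. With MC replicate 1 alone 942 rose and 452 fell, and the rescaled signal gave 2342 and 1140.

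In 1/7MC+Pyr+FGF against MC, fibroblast markers stayed higher, with 28 of 30 up and 2 down and a median of 1.39. POSTN rose by 3.46 ± 0.15, COL1A2 by 3.37 ± 0.21, COL3A1 by 2.69 ± 0.20 and COL1A1 by 2.15 ± 0.28. Junction genes fell in 11 of 19 cases and rose in 1, with a median of -0.82, EPCAM by 3.03 ± 0.12, ESRP1 by 2.78 ± 0.15 and CLDN7 by 2.50 ± 0.15 on the log2 scale, and CDH1 changed by -2.10 ± 0.20. TGF-beta response genes rose in 11 of 19 cases and none fell (13 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2; median 0.84). Camera gave adjusted p = 1.35e-13, 1.22e-06 and 5.8e-06 for these lists (adjusted p = 0.181, 0.111 and 0.181 with an estimated correlation). When only MC replicate 1 was kept, 22 of 31 fibroblast markers rose and 1 fell, 11 of 19 junction genes fell and 1 rose, and 9 of 20 TGF-beta genes rose. Interferon response genes had 6 rises and 1 fall in 18 (7 and 1 adjusted over the list alone; median 0.48; camera adjusted p = 0.151, or 0.0193 against MC replicate 1 alone). Cholesterol genes rose in 11 of 22 cases and none fell (12 rose adjusted over the list alone; no fall at an unadjusted p or by DESeq2; median 0.42), with IDI1 at 0.81 ± 0.11 and HMGCS1 at 0.78 ± 0.12. For them camera gave adjusted p = 0.00725 (adjusted p = 0.527 with an estimated correlation), 0.0853 without MC replicate 1 and 0.0717 without 1/7MC+Pyr+FGF replicate 2, and 5 rose against MC replicate 1 alone. Leaving out 1/7MC+Pyr+FGF replicate 2 gave a median of 0.24 and 2 falls, and leaving out MC replicate 1 gave 1 fall. Fibroblast falls numbered 1 without MC replicates 2 or 3 or 1/7MC+Pyr+FGF replicates 1 or 3. The junction median was -0.11 in the signal as deposited.

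Beside fibroblast markers at 1.39 camera called 5 more lists. Neural ectoderm genes fell in 7 of 11 cases and rose in 1, with DLL1 at -3.89 ± 0.40. Mesoderm genes rose in 7 of 12 cases and fell in 2, with TWIST1 at 1.72 ± 0.12, and endoderm genes rose in 5 of 10 and none fell. Endothelial and blood markers rose in 7 of 12 cases and none fell (8 rose adjusted over the list alone), with TAL1 at 2.37 ± 0.21. In the last 2 lists none fell at an unadjusted p or by DESeq2. Immediate early and heat shock genes fell in 7 of 18 cases and rose in 3, with EGR1 at -3.17 ± 0.12. The 5 lists had adjusted p = 0.00640, 0.0366, 0.00725, 0.0233 and 0.0255, and with an estimated correlation adjusted p = 0.229, 0.210, 0.181, 0.342 and 0.342. None was called without MC replicate 1 (adjusted p = 0.229 for endoderm and 0.0797 for the others), and only the neural list without 1/7MC+Pyr+FGF replicate 2 (the others up to 0.0717). Endoderm had adjusted p = 0.0670 without 1/7MC+Pyr+FGF replicate 3, and the immediate early list 0.0740 under the stricter filter. Set against MC replicate 1 alone, 4 of 13 neural genes fell and none rose, 4 of 12 mesoderm genes rose and 1 fell, 5 of 12 endoderm and 1 of 12 endothelial genes rose, and 5 of 18 immediate early genes fell and 1 rose. The neural rise was lost when any of 4 libraries was left out. Endothelial rises numbered 4 without MC replicate 2 or 1/7MC+Pyr+FGF replicate 2, and endoderm had 1 fall without MC replicate 1 or any 1 of the 1/7MC+Pyr+FGF replicates.

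NANOG was higher in 1/7MC+Pyr+FGF than in MC, at 90.5 against 38.4 CPM (1.24 ± 0.15), and POU5F1 did not pass (0.07 ± 0.12). Of 14 shared pluripotency genes 2 rose and 6 fell (camera adjusted p = 0.074), beside a median of 1.39 for the fibroblast markers. Glycolysis genes fell in 11 of 23 cases and rose in 2 (12 and 2 adjusted over the list alone; median -0.23, and 0.01 in the signal as deposited, whose median over all genes was shifted by 0.22). Testing by camera gave adjusted p = 0.0064 (adjusted p = 0.181 with an estimated correlation) and 0.0797 without MC replicate 1, and 4 fell against MC replicate 1 alone. Glycolysis rises numbered 1 without MC replicates 2 or 3 or 1/7MC+Pyr+FGF replicates 2 or 3. LDHA changed by -1.75 ± 0.14, PDK1 by -1.19 ± 0.14 and HK2 by -0.60 ± 0.14, and VIM rose by 0.57 ± 0.13. LIN28A (-0.42 ± 0.10), DNMT3B (-0.40 ± 0.09), SPRY4 (1.21 ± 0.29), ETV4 (0.62 ± 0.15), MPC1 (0.74 ± 0.16), PKM (-0.34 ± 0.08) and SLC16A1 (0.45 ± 0.11) passed with 12 libraries and missed the threshold against MC replicate 1 alone (adjusted p from 0.0768 to 0.336). The largest rises were ITGA1 (3.84 ± 0.40), ATP6AP1L (3.72 ± 0.18), PLVAP (3.67 ± 0.25), POSTN, P3H2 (3.39 ± 0.19) and COL1A2. The largest falls were DMD (-8.92 ± 1.50), FOSB (-5.45 ± 0.26), ACTA1 (-4.24 ± 0.17), FEZF1 (-4.21 ± 0.18), CHRDL1 (-4.18 ± 0.78) and GBF1 (-3.91 ± 0.68). Measured against MC replicate 1 alone DMD (-2.40), CHRDL1 (-0.53) and GBF1 (-0.83) did not pass. In all, 4527 genes changed, 2377 up and 2150 down. The number was 3015 without MC replicate 2, 1723 against MC replicate 1 alone (842 up and 881 down), and the signal as deposited gave 1819 up and 273 down.

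Of the 6268 genes that differed between 1/7MC and MC, 3165 (50.5%) still differed the same way in 1/7MC+Pyr and 3134 in 1/7MC+Pyr+FGF, while 48 and 119 differed the other way. FOSB, ITGA1, ATP6AP1L, PLVAP, FEZF1 and HEATR1 (-3.51 ± 0.66; -0.31 and not passed against MC replicate 1 alone) had the largest changes shared by 1/7MC and 1/7MC+Pyr+FGF. Independent lists would share 502 higher and 391 lower genes for 1/7MC+Pyr, where 1776 and 1389 were shared, and 564 and 458 for 1/7MC+Pyr+FGF, where 1638 and 1496 were shared. Simulated unchanged groups shared at most 1 gene. Covariances were 0.723 and 0.66, against 0.0397 and 0.0417 when simulated. The 3 MC libraries cannot be split with like counting on both sides, so part of the excess may come from shared controls. Against MC replicate 1 alone 1176 (34.2%) and 1213 (35.3%) of 3438 genes still differed.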

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

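All tests weighed in this part were chosen after the results they concern had been seen.

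Entries sharing an identifier with another take no part in the comparisons. Of 215 tested in a fit keeping all entries, 18 changed between 1/7MC+Pyr+FGF and 1/7MC, 7 up and 11 down. Of 13920 genes in the main fit 3842 changed, a larger share, and some left-out entries repeat counts.

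MC replicates 2 and 3 stood apart from the other 10 libraries. In both, 17 genes had at most 2 counts while each of the other 10 libraries had at least 20, and 0 genes did so for any other pair of libraries of a group; MRPL24 and PREB, with 1 and 2, and 0 and 0 counts there against 1728 and 1829 in MC replicate 1, are examples. These values are what counting with other gene models would give. A wrong label of MC replicate 1 is argued against: 28 of 30 fibroblast and feeder markers were lower in it than in each of the 9 libraries of the other groups, and 28 were in MC replicates 2 and 3. No biological explanation was tested, since all 3 libraries carry the same group label.

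Fibroblast and feeder markers were higher in 1/7MC than in MC. The other gene models of MC replicates 2 and 3 are argued against as the whole cause, because the median against MC replicate 1 alone was 1.91. A gene length trend is argued against as well, since removing it left a median of 1.79 with 28 of 30 members up. A larger share of RNA from feeder cells and a change within the stem cells cannot be told apart: 24 of 30 members lay more than 2 standard errors from the list's median (quartiles 0.99 and 2.92), but there is no library of feeder cells or of stem cells alone, and the labels do not give the feeders' species.

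Interferon response genes were lower with FGF. A smaller share of RNA from feeder cells is argued against as the sole source: the 15 fibroblast markers at least 4-fold higher in 1/7MC+Pyr than in MC had a median of -0.76 with FGF (quartiles -0.94 and -0.50), against -1.64 for the interferon list (quartiles -1.89 and -0.78). Removing a gene length trend left an interferon median of -1.65. Its value closest to 0 with 1 of the 6 libraries left out was -1.44, without 1/7MC+Pyr+FGF replicate 1. A response to FGF in either cell type remains open as a hypothesis, and no test here separates the cell types.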

How the results depend on the processing

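The fits with MC replicate 1 alone, a length trend removed, all entries kept and the rescaled signal were chosen after the data were seen. For the single genes named, 5598 of 5899 alternative values kept direction and side of the threshold, 252 lost the threshold, 49 gained it and 0 reversed; for the gene lists 1206 of 1365 did, 143 lost it and 16 gained it.

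Comparisons follow in the order 1/7MC against MC, 1/7MC+Pyr against 1/7MC, 1/7MC+Pyr+FGF against 1/7MC+Pyr, 1/7MC+Pyr+FGF against 1/7MC, 1/7MC+Pyr against MC and 1/7MC+Pyr+FGF against MC. With 1 library left out the changed genes numbered 5001 to 6953, 1423 to 2252, 127 to 439, 2697 to 3209, 2571 to 5151 and 3015 to 5337, and the lists called 14 to 15, 6 to 8, 11 to 14, 9 to 18, 9 to 13 and 3 to 10. Requiring a log2 fold change of at least 1 left 2420, 771, 137, 1147, 1463 and 1514 genes. The signal named TPM gave 2028, 558, 56, 823, 1030 and 2092 with a pseudocount of 1, 2037, 501, 49, 760, 1081 and 2054 with 0.1, and 3855, 1246, 66, 1717, 1547 and 2197 with no filter. Against MC replicate 1 alone, 3438, 1394 and 1723 genes changed in the comparisons with MC, where 1 library in place of 3 leaves less to test with. For FGF on top of pyruvate DESeq2 called 863 genes, and the replicate number as a block left 181. Camera with an estimated correlation called 1, 0, 1, 0, 0 and 0 lists; fry called 22, 15, 10, 22, 19 and 17. Of the list calls followed, fry lost 8 and gained 11, removal of the length trend lost 4 and the stricter filter lost 8.

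Genes that moved opposite to the change between 1/7MC and MC numbered, with 1 library left out, 1184 to 2203 with pyruvate, 72 to 415 with FGF on top and 1863 to 2909 with both, with slopes of -0.350 to -0.226, -0.0759 to -0.0344 and -0.414 to -0.270. The signal named TPM gave 458, 27 and 503 genes, and a first change of at least 1 left 992 with pyruvate and 1221 with both. With FGF on top DESeq2 gave 436 and the replicate block 104. The slope with pyruvate was -0.33 by DESeq2 and -0.31 with no filter. In the signal named TPM the slope with both was -0.35, and with FGF on top it reversed to 0.0013. Except where a smaller set of genes or libraries is named, the cause was not tested.

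The replicate numbers do not pair the libraries. Correlations between libraries with the same number ran from -0.32 to 0.33, and 3 of 12 libraries correlated best with their own number. At these depths the self-test recovered 8 to 13 of 50 genes changed by 0.5 on the log2 scale, so small changes are under-counted.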

Other observations

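The tests of other splits were chosen after the results had been seen; the lists in the next paragraphs were fixed in advance.

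Several fixed lists held single genes with large changes and no shared direction in 1/7MC against MC. Of 12 naive pluripotency genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; median -0.29, but 0.27 in the rescaled signal, -0.02 as deposited, and -0.05 and -0.10 without MC replicates 1 and 2; camera adjusted p = 0.748, fry adjusted p = 0.00103), with TBX3 at 3.51 ± 0.25 and STAT3 at 1.53 ± 0.10. Of 16 primed pluripotency genes 4 rose and 8 fell (median -0.27, but -0.18 in the rescaled signal and -0.07 as deposited; camera adjusted p = 0.299), with SFRP2 at 1.91 ± 0.10 and POU3F1 at -2.09 ± 0.13. In the trophectoderm list 4 of 14 rose and 6 fell (median -0.33, but -0.50 in the rescaled signal; camera adjusted p = 0.335, fry adjusted p = 0.00212), with GATA3 at 3.93 ± 0.32 and KRT7 at -2.28 ± 0.15. Endothelial and blood markers rose in 5 of 12 cases and fell in 3 (median 0.74, but -0.03 in the rescaled signal; camera adjusted p = 0.384), with PECAM1 at 3.38 ± 0.58. Chromatin and imprinting genes rose in 7 of 22 cases and fell in 8 (camera adjusted p = 0.967), with the imprinted genes IGF2 at 3.75 ± 0.19 and DLK1 at -2.26 ± 0.20. With pyruvate, TBX3 (-2.40 ± 0.23), SFRP2 (-1.83 ± 0.10) and IGF2 (-1.50 ± 0.17) fell. Against MC replicate 1 alone the counts up and down were 3 and 0 of 12 naive, 3 and 7 of 16 primed, 3 and 6 of 14 trophectoderm, 4 and 2 of 12 endothelial and 5 and 5 of 22 chromatin genes.

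Of 18 genes of mitochondrial biogenesis 2 rose and 6 fell in 1/7MC against MC (median -0.14, but -0.05 in the rescaled signal and -0.01 as deposited; camera adjusted p = 0.213), with PPRC1 at -0.58 ± 0.09 and FIS1, a mitochondrial fission gene, at 0.87 ± 0.14; 3 fell without MC replicate 2 or 1/7MC replicate 1, 1 rose without MC replicates 2 or 3 or 1/7MC replicates 2 or 3, and 1 rose and 2 fell against MC replicate 1 alone. Of 17 fatty acid oxidation genes 4 rose and 2 fell (camera adjusted p = 0.911), with ACADVL at 1.11 ± 0.11 and PPARA at -1.24 ± 0.22; without MC replicate 1 2 rose and 4 fell, without 1/7MC replicate 3 2 rose and 1 fell, without MC replicate 2 3 rose and 1 fell, and 4 rose and 1 fell against MC replicate 1 alone. With pyruvate ACADVL fell by 0.74 ± 0.11 on the log2 scale. Of 21 p53 and apoptosis genes 7 rose and 1 fell (median 0.21, or 0.13 without 1/7MC replicate 2; camera adjusted p = 0.223), with GADD45B at 0.68 ± 0.11 and CDKN1A, a cell cycle inhibitor, at -0.49 ± 0.08; 2 fell without MC replicate 1, and 3 rose and 1 fell against MC replicate 1 alone.

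The 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. In the order used above for the alternatives, the real splits changed 6268, 2525, 384, 3842, 3949 and 4527 genes. The highest of the other splits changed 0 by edgeR in each comparison (at an unadjusted p at most 1316, 1542, 3507, 1365, 1978 and 1974; DESeq2 was not run on splits), so 1 of the 10 splits, the real one, was as large. Lists called were 15, 6, 12, 15, 14 and 10, and at most 14, 14, 10, 13, 9 and 8 in other splits, with 1, 7, 1, 1, 1 and 1 of the 10 splits as large. Genes moving opposite to the first change numbered 1948, 226 and 2553 with pyruvate, FGF on top and both, with 0 by edgeR in the highest other split; slopes were -0.34, -0.063 and -0.40, against -0.117, -0.0612 and -0.169 in the most negative other split. With FGF on top, another split reached 3507 genes at an unadjusted p, against 2632 for the real one. It set 1/7MC+Pyr+FGF replicates 1 and 3 and 1/7MC+Pyr replicate 2 apart, and goes with a gene length trend. Medians of the shortest less the longest genes were 0.375, 0.093 and -0.069 in these, against -0.252 to -0.237.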
